A study of Mus musculus with 36 samples.

How the data were processed

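The material was total RNA of primary cortical astrocyte cultures from newborn C57B/6 mice (the growth protocol names cortex or hippocampus), grown to about confluence and given about 100 nM dexamethasone or vehicle for 0.25 h, 1 h, 2 h, 4 h, 6 h, 12 h, 18 h or 24 h. Per the labels, biotinylated cRNA was hybridized to Illumina BeadChips and read with GenomeStudio, whose version is not given in the sources used here. There are 36 arrays in 16 groups: 12 groups of 2 and 4 groups of 3 (2 h and 4 h). Whether replicates are separate cultures is not stated, and the p-values therefore measure the spread between these samples.

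The deposited series table gives 1 intensity per probe and array for 45281 probes, on a linear scale from 44.8 to 49460.6. The authors had quantile normalized these intensities: apart from the 10 lowest, the sorted values of any pair of columns differ by at most 0.5, and array medians run from 93.7 to 94. No background had been subtracted. The other deposited table holds 36 intensity columns and 36 detection p columns whose names match no sample label; these were not used here, and only its gene symbols were read. A joint background correction and normalization with negative controls (neqc) and a filter on detection p were planned and gave way to the following. Intensities were corrected by normexp with an offset of 16 and put on the log2 scale. A background level was taken from the mode of all intensities (70.2) and the spread below it, mirrored: its 99th percentile was 91.7, or 5.83 on the corrected log2 scale. Probes above it on at least 2 arrays were kept (29540); on each array 51.4% to 51.5% of all probes lay above it. Signal over background, not read depth, limits these values, and folds of genes not above background in 1 group are given as "at least", computed against that level. Late-minus-early values with group means under that level raised to it were added after the results were seen.

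Of the probes, 45223 carried 1 symbol; 40 whose symbol a spreadsheet had turned into a date and 18 with several symbols were left out. Each symbol was represented by its probe with the highest mean, which left 20637 genes; 12031 symbols were current RefSeq symbols, 3953 were updated through a unique synonym and 4653 had no match. All 36 arrays were fitted with limma 3.58.1 in R 4.3.3, with 16 group means, empirical Bayes variances (20 residual and 5.23 prior degrees of freedom) and Benjamini-Hochberg adjustment within each comparison, calls being made at an adjusted p under 0.05. The comparisons were dexamethasone minus vehicle averaged over the 8 times, at each time, late (12, 18, 24 h) minus early (1, 2, 4 h) responses, and an F-test with 7 degrees of freedom across the 8 times. Comparisons at different times share no arrays in their means, but they share the spread of each gene, which was estimated over all 36 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

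The 25 gene lists, the comparisons and the naming rule were set before the data were examined. The lists cover glucocorticoid-receptor targets; corticosteroid receptors and chaperones; cytokines; NF-kappaB feedback; interferon-stimulated genes; complement; immediate early genes; astrocyte markers; reactive astrocyte genes; glucose, fatty acid and cholesterol metabolism; cell division; extracellular matrix; clock genes; stress response; heat shock; growth factors; junctions and transport; and markers of microglia, oligodendrocyte lineage, neurons, fibroblasts, endothelium and ependyma. Some lists share members, for instance 10 of 24 astrocyte markers and 5 of 11 fibroblast markers stand in another list; none of the microglia or oligodendrocyte markers does. On all 36 arrays, 17 of 19 microglia markers and 7 of 14 oligodendrocyte markers lay above background, but only 7 of 24 cytokine genes and 2 of 10 endothelial markers. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the 25 lists. An estimated correlation and fry were alternatives. The smallest p-values rest on the preset correlation. For receptor targets at 2 h and cell division genes at 24 h, for instance, some alternatives gave adjusted p many orders of magnitude larger, still past the threshold. Over all comparisons with vehicle, calls that held with the estimated correlation numbered 8 of 11 for the average, 0 of 0 at 0.25 h, 1 of 6 at 1 h, 6 of 9 at 2 h, 5 of 6 at 4 h, 8 of 11 at 6 h, 5 of 13 at 12 h, 8 of 11 at 18 h and 5 of 11 at 24 h, and 7 of 11 for late minus early. Where a list's call is said to be lost under an alternative, the highest adjusted p printed for it is the highest over its alternatives.

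Genes named in the text are, for the average, the 12 called genes with the largest rise and the 12 with the largest fall whose difference had the same sign at 6 or more times; at single times, the 4 largest each way whose arrays do not overlap (chance gives 33.3% for 2 against 2 arrays); for late minus early, the 6 largest each way; for the F-test, the 6 smallest p. Up to 4 called members per list were eligible, or 2 as values where none was called, and Nr3c1, Fkbp5, Tsc22d3 and Per1 are always reported. Of the eligible list members, the report prints mainly those that kept their call with every array left out in turn, a choice made after these values were seen, and says where a printed gene did not. A few genes that the naming rule selects are not reported here.

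Whether replicate numbers pair the samples was checked with the correlation of residuals between equal numbers of both treatments: 0.8 at 0.25 h, 0.73 at 1 h, 0.86, 0.68 and 0.77 at 2 h, 0.57, 0.35 and 0.54 at 4 h, 0.03 at 6 h, 0.51 at 12 h, -0.05 at 18 h and -0.13 at 24 h. Of 18 pairs, 12 exceeded 0.1 and 14 correlated best with their own number. In groups of 2 arrays both pairs of a time share their correlation, so the 18 are not separate observations. With at least 3 pairs required, all above 0.1, only 2 h and 4 h counted as paired. Counts with the number as a block are given beside the results there, but that block was fitted at every time, paired or not. On simulated data with the same groups, the average recovered 91.2% of 1.5-fold changes, late minus early 12.1% and single times 2.9% to 14.7%. Single times recovered between 30.3% (1 h and 6 h) and 69.7% (2 h) of 2-fold changes and between 90.9% and 97% of 4-fold changes. Late minus early recovered 70.6% of 2-fold and 97% of 4-fold changes. The simulation gave a gene the same spread at every time and no tie between equal replicate numbers. The real arrays differed in both, so these shares do not rank the times.

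Alternatives tried were no background correction, the deposited values on the log2 scale, normexp with an offset of 50, median centring, cyclic loess, no filter and 2 stricter filters, every probe tested, trended and robust variances, array weights, the replicate block, a 1.5-fold minimum, the arrays of 1 time alone, and leaving out each array in turn. The offset of 50, cyclic loess, the filter at a mean intensity of 150, leaving out the 12 h or the 0.25 h and 1 h arrays, the 12 h and late-minus-early lists without vehicle 12 h replicate 1 and a crossed block at 24 h were added after the data were seen. A slide block was not run, since no slides are named.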

Results

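Gene expression was measured on 36 arrays of mouse cortical astrocyte cultures that had received about 100 nM dexamethasone, a synthetic glucocorticoid, or vehicle for 0.25 h, 1 h, 2 h, 4 h, 6 h, 12 h, 18 h or 24 h. The 2 h and 4 h groups held 3 arrays per treatment and the other groups 2, which makes 18 dexamethasone and 18 vehicle arrays. At each time the question was which transcripts differed between treated and vehicle cultures, and across the series which responses were shared by the 8 times and which differed between 12, 18 and 24 h and 1, 2 and 4 h. Changes are log2 differences, dexamethasone minus vehicle, with the standard error (SE), and a gene is called changed at a limma adjusted p under 0.05 among 20637 genes. The p-values measure only the spread between these samples, which may be technical in part, and the number of arrays limits the precision.

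Period 1 (Per1), Errfi1, Tsc22d3 and the connexin gene Gjb6 were among 14 genes called at 1 h, and no gene was called at 0.25 h. The counts were 146 at 2 h (120 higher, 26 lower), 488 at 4 h (320 higher, 168 lower), 429 at 6 h (288 higher, 141 lower), 1171 at 12 h (455 higher, 716 lower), 746 at 18 h (342 higher, 404 lower) and 799 at 24 h (380 higher, 419 lower). With array weights the counts were 2305 at 6 h, 293 at 12 h and 3841 at 18 h, so which time had the most calls depends on the fit. All 13 genes higher at 1 h were also higher at 2 h (0.0756 expected for independent lists), and 113 of the 120 higher at 2 h were higher at 4 h (1.86 expected). Between 18 h and 24 h, 262 higher genes (6.3 expected) and 286 lower genes (8.2 expected) were shared. The spread of each gene was estimated over all times together, so calls at different times are not independent. The expected numbers may therefore be too low. Per1, Tsc22d3, Gjb6, Pdk4, Errfi1, Klf9, Adm, Fam107a, Tcim (listed as 1810011O10Rik) and 2310051E17Rik, a further probe for Klf9, were each called higher at 7 of the 8 times. The exception was 0.25 h, and no gene was called at all 8.

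**Figure D1:**
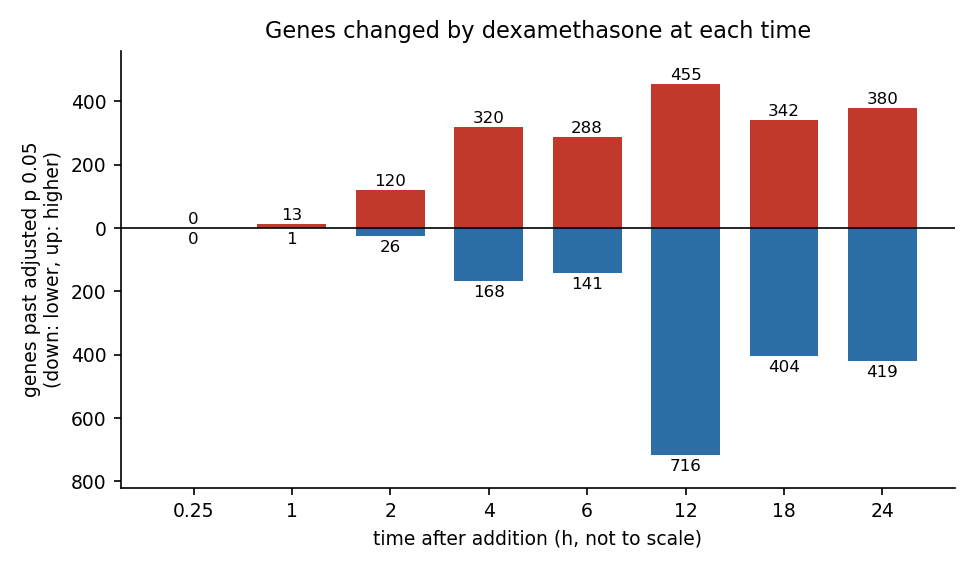
Number of genes called higher (upward) and lower (downward) under dexamethasone against hours of treatment, with limma adjusted p under 0.05 among 20637 genes. The counts go from 0 at 0.25 h to 455 higher and 716 lower at 12 h. With array weights, not shown, 12 h had 293 called genes and 18 h 3841.

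Averaged over the 8 times, Fam107a, Lcn2, Gjb6 and Fkbp5 had the largest rises and Ch25h, Ccl4 and Cxcl10 the largest falls. Fam107a, which encodes an actin-binding protein, rose by 3.60 (SE 0.11, 12.1-fold, adjusted p = 4.1e-19), the siderophore-binding lipocalin Lcn2 by 3.43 (SE 0.11, 10.8-fold) and Gjb6, connexin 30 of astrocyte gap junctions, by 3.38 (SE 0.07, adjusted p = 1.8e-22), with 18 arrays per treatment. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, rose by 3.22 (SE 0.08, 9.33-fold), Tsc22d3 (the leucine zipper protein GILZ) by 2.14 (SE 0.07) and Per1 by 1.86 (SE 0.12). Enzymes and a transporter followed: the branched-chain aminotransferase Bcat1 (2.88), the glutamate carboxypeptidase Folh1 (2.77), the sulfotransferase Sult1a1 (2.64), proline dehydrogenase Prodh (2.52), the pyruvate dehydrogenase kinase Pdk4 (2.40) and the steroid sulfate carrier Slc10a6 (at least 3.08-fold). Ipas, the listing of a second probe for the transcription factor gene Hif3a, was at least 6.89-fold higher, while the probe listed as Hif3a did not pass (0.12, adjusted p = 0.42). The lipid droplet coat gene Plin4 (listed as S3-12) rose by 2.72. Nr3c1, the glucocorticoid receptor itself, did not pass (-0.25, SE 0.14, adjusted p = 0.34).

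Ch25h, which makes 25-hydroxycholesterol, had the largest fall (-2.45, SE 0.13, 5.48-fold, adjusted p = 1.3e-13), followed by the chemokines Ccl4 (-1.78, SE 0.11) and Cxcl10 (-1.70, SE 0.09). Phlda1 (-1.37), the predicted locus LOC100048556 (-1.30), the ligand gene Wnt7a (-1.28), the prokineticin receptor Prokr1 (-1.23), Ccl3 (-1.20, or -0.79 with no background correction), 2810459M11Rik (-1.15), the clock output factor Dbp (-1.12, SE 0.06), stanniocalcin Stc1 (-1.10) and the replication helicase subunit Mcm3 (-1.08, SE 0.13) also fell. The test called 2439 genes (1066 higher, 1373 lower). The count was 454 (326 higher, 128 lower) when a 1.5-fold change was required as well.

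Among the fixed gene lists, the classic glucocorticoid-receptor targets rose and the cell division genes fell most widely on the average of the 8 times. Of 30 receptor targets, 23 rose, 0 fell and 7 did not pass (adjusted over the list alone, 25 higher and 1 lower, median 1.09, camera adjusted p = 1.2e-54). Of 30 cell division genes, 24 fell, 0 rose and 6 did not pass (25 lower adjusted over the list alone, median -0.39, adjusted p = 8.5e-22), among them the replication genes Cdc6 (-0.78), Mcm5 (-0.76) and Tk1 (-0.66). Of 24 cytokines, chemokines and inflammatory enzymes, 15 fell, 0 rose and 9 did not pass (17 lower adjusted over the list alone, median -0.36, adjusted p = 6.2e-12), Tnf by -0.71 among them (-0.37 with no background correction). Only 7 of these 24 genes lay above background on all arrays, so the size of the list's fall is uncertain here and at single times. Of 22 interferon-stimulated genes, 9 fell, 0 rose and 13 did not pass (10 lower adjusted over the list alone, median -0.20, adjusted p = 0.00034), with Oasl2 at -0.50 and Irf1 at -0.33.

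Of 24 astrocyte markers, 9 rose, 1 fell and 14 did not pass (10 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 1.8e-06), with Gjb6, glutamine synthetase Glul (1.52), Cbs (1.13) and Ndrg2 (0.80) among the risers. Of 24 reactive astrocyte genes, 8 rose, 5 fell and 11 did not pass (9 and 5 adjusted over the list alone, median 0.07, adjusted p = 1e-04). The risers included Lcn2, the small heat shock protein gene Hspb1 (1.87) and Sphk1 (1.43). Of 21 tight junction, gap junction and transport genes, 4 rose, 1 fell and 16 did not pass (4 and 1 adjusted over the list alone, median 0.06, adjusted p = 0.009), with Cldn10 at 0.84. Of 23 genes of fatty acid use and lipid droplets, 5 rose, 1 fell and 17 did not pass (5 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.009). The triglyceride lipase Pnpla2 rose (0.78) and the lipoprotein lipase Lpl fell (-0.46). The calls of these 8 lists held with an estimated correlation. Over all settings the medians of some ran further: -0.42 to -0.23 for cytokines, 0.08 to 0.17 for astrocyte markers, 0.03 to 0.09 for junctions and 0.07 to 0.15 for fatty acid genes.

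Lists with small medians passed too and lost their call with an estimated correlation. Of 21 genes of glucose, glycogen and glutamate handling, 4 rose, 1 fell and 16 did not pass (4 and 1 adjusted over the list alone, median 0.06, adjusted p = 0.045, and adjusted p = 0.085 with an estimated correlation). Of 9 heat shock genes, 2 rose and 7 did not pass (3 higher adjusted over the list alone, median 0.03, adjusted p = 0.048, and adjusted p = 0.077 with an estimated correlation). Of 11 fibroblast, meningeal and pericyte markers, Ogn alone rose (0.62, 3 higher adjusted over the list alone, median 0.09, adjusted p = 0.045, and adjusted p = 0.22 with an estimated correlation). Each of the 3 calls also ended without some single arrays, and the highest adjusted p over all settings was 0.091, 0.11 and 0.22. Their medians ran from 0.02 to 0.08, from -0.01 to 0.1 and from 0.05 to 0.13.

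Lists that did not pass on the average of the 8 times held single genes that did. The histamine-forming enzyme Hdc rose by 1.46, the claudin Cldn11 by 1.54 and Enpp2 by 0.84. The NF-kappaB inhibitor Nfkbia rose by 1.18 and the mRNA decay factor Zfp36 by 0.77, and Nr1d2 (-0.56) and Trib3 (-0.57) fell. Hspa1a, of the heat shock list that did pass, rose by 0.80. Counts higher and lower were 2 and 2 of 13 for NF-kappaB feedback regulators (median -0.07, mean 0.04), 2 and 3 of 19 for immediate early genes (-0.12) and 1 and 0 of 12 for complement and antigen presentation (0.01). They were 3 and 5 of 14 for circadian clock genes (0.08), 1 and 3 of 20 for the unfolded protein and amino acid stress response (-0.01) and 6 and 6 of 28 for growth factors and their binding proteins (-0.08, mean -0.01, camera direction up). For further lists they were 0 and 1 of 10 for corticosteroid receptors, chaperones and steroid-converting enzymes (-0.07), 1 and 0 of 21 for cholesterol synthesis and uptake (-0.03) and 3 and 1 of 27 for extracellular matrix genes (median -0.01, mean 0.04). Marker lists gave 1 and 2 of 19 for microglia and macrophages (-0.14), 2 and 0 of 14 for the oligodendrocyte lineage (median -0.02, mean 0.14), 0 and 0 of 12 for neurons (-0.01), 2 and 0 of 10 for endothelium (0.02) and 1 and 2 of 8 for ependyma (-0.24). Adjusted over the list alone these counts went up to 2 lower for the receptor list, 6 higher for extracellular matrix, 5 higher for clock genes, 8 and 7 for growth factors and 5 lower for ependyma. They stayed as they were for the others. The camera adjusted p ran from 0.17 for microglia to 0.91 for the stress response. The oligodendrocyte list passed without vehicle 12 h replicate 1 (0.09, adjusted p = 0.0086) and without the 12 h arrays (0.08, adjusted p = 0.0064). Without vehicle 12 h replicate 2 the immediate early list (-0.2, adjusted p = 0.025) and the microglia list (-0.27, adjusted p = 0.00012) passed, but without vehicle 12 h replicate 1 their medians were -0.04 and -0.01. Fry called the corticosteroid receptor list (adjusted p = 0.0028).

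**Figure D2:**
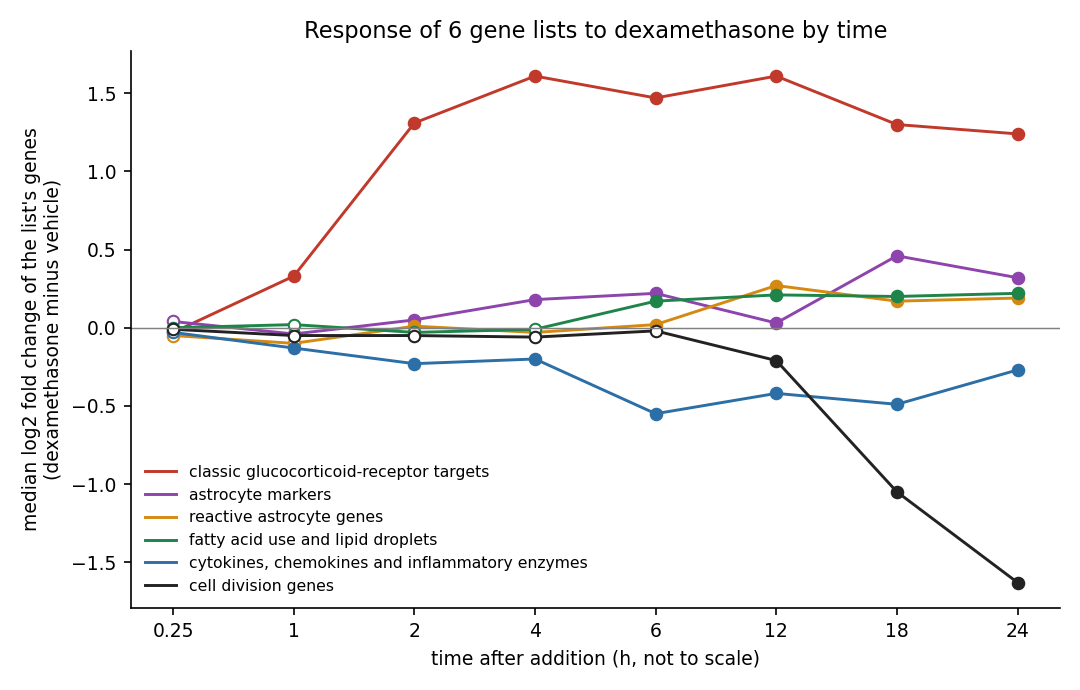
Median log2 change (dexamethasone minus vehicle) of 6 fixed gene lists against hours of treatment; filled circles mark a camera adjusted p under 0.05. The median of the cell division genes went to -1.05 at 18 h and -1.63 at 24 h, and that of the classic receptor targets stood at 1.31 at 2 h.

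After 0.25 h, no transcript passed. Fkbp5 (0.03, SE 0.23), Tsc22d3 (-0.03, SE 0.19), Per1 (0.17, SE 0.34) and Nr3c1 (0.18, SE 0.41) all had an adjusted p of 1 with 2 arrays per group. Limma called 0 genes, with 206 at an unadjusted p under 0.05, and the count was 0 as well with array weights, with trended and robust variances, with a replicate block and with the arrays of that time alone. None of the 25 lists passed. The sensor of viral RNA Ifih1 had the largest value among the named list members (-1.17, SE 0.25, adjusted p = 1). The 4 vehicle arrays of 0.25 h and 1 h lay above 13 vehicle arrays of 2 h to 24 h (vehicle 12 h replicate 1 left out) by a median of 1.93 for microglia markers, 1.46 for oligodendrocyte markers, 0.6 for ependymal markers and 0.52 for astrocyte markers.

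After 1 h, Per1, Tcim and Errfi1 were among the single genes that rose. Per1, a clock gene with glucocorticoid response elements, rose 4-fold (2.00, SE 0.34, adjusted p = 0.0089, dexamethasone 12.01, SD 0.1, vehicle 10.01, SD 0.23, 2 arrays each), Tcim by 2.05 (SE 0.28, adjusted p = 6e-04), and Errfi1, an inhibitor of the epidermal growth factor receptor, by 1.77 (SE 0.21, adjusted p = 0.00021). Fam107a (1.70), the locus A930039A15Rik (1.75), Gjb6 (1.5), Tsc22d3 (1.23) and Pdk4 (1.16) rose too, and the Polycomb gene Pcgf5 (listed as 5830406C17Rik, -1.32, SE 0.23) was the only gene that fell, while the brighter probe listed as Pcgf5 did not pass (0.07, adjusted p = 1). Fkbp5 (0.49, adjusted p = 1), Tnf (-1.58, adjusted p = 0.25) and Ier3 (-1.14, adjusted p = 0.1) did not pass. The test called 14 genes (13 higher, 1 lower), but 5 without dexamethasone 1 h replicate 1, 7 without replicate 2, 1 without vehicle 1 h replicate 1 and 5 without replicate 2, Errfi1 keeping its call in all 4 cases. The calls of Tcim and Gjb6 ended without vehicle 1 h replicate 1 (1.90 and 1.25, adjusted p = 0.087 each), and Per1 lost its call whichever array was left out (1.84 to 2.16, adjusted p from 0.11 to 0.3). Without dexamethasone 1 h replicate 1 the calls of Fam107a (1.47, adjusted p = 0.7), A930039A15Rik (1.33, adjusted p = 0.89), Tsc22d3 (1.12, adjusted p = 0.23), Pdk4 (1.03, adjusted p = 0.7) and Pcgf5 (-1.13, adjusted p = 0.59) ended. Each of these 5 ended without vehicle 1 h replicate 1 or 2 as well. A fit to the arrays of this time alone called 0 genes.

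Of the 30 receptor targets, 6 rose at 1 h, 0 fell and 24 did not pass (11 higher adjusted over the list alone, median 0.33, camera adjusted p = 4e-26), which held with an estimated correlation. Immediate early genes, such as Ier3, had 0 of 19 called (1 lower adjusted over the list alone, median -0.30, adjusted p = 0.002). Cytokines and chemokines had 0 of 24 called (2 lower adjusted over the list alone, median -0.13, adjusted p = 0.0023). NF-kappaB feedback regulators had 0 of 13 called (2 higher adjusted over the list alone, median 0.13, adjusted p = 0.02). Ependymal markers had 0 of 8 called (0 adjusted over the list alone, median 0.25, adjusted p = 0.003). The cytokine median was -0.08 on the log2 of the deposited values. For these 4 lists, adjusted p = 0.38 with an estimated correlation and 0.63 by fry. Cholesterol genes had 0 of 21 called (0 adjusted over the list alone, median -0.04, adjusted p = 0.049, adjusted p = 0.15 with an estimated correlation and 0.63 by fry). Microglia markers (median 0.21) did not pass, but did in 2 of 5 alternatives (lowest camera adjusted p = 0.015).

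By 2 h, Gjb6, Lcn2 and Fkbp5 stood among the largest rises. Gjb6 rose 13.1-fold (3.71, SE 0.16, adjusted p = 4.7e-14), Lcn2 10.9-fold (3.45, SE 0.26), Fkbp5 10.8-fold (3.43, SE 0.18, dexamethasone 10.8, SD 0.21, vehicle 7.37, SD 0.23, 3 arrays each) and Fam107a 9.28-fold. Phlda1 (-2.19, SE 0.32), Ch25h (-2.03) and Ccl4 (-1.60) fell, as did the neurotrophic ligand gene Artn (-1.43), whose call ended without dexamethasone replicate 3 (-1.20, adjusted p = 0.052) or vehicle replicate 1 (-1.18, adjusted p = 0.05). Per1 (2.25), Tsc22d3 (2.17), Errfi1 (2.41), Pdk4 (2.39) and Plin4 (2.46) rose, and Bhlhe40, a clock repressor listed as Bhlhb2, fell (-0.84). The test called 146 genes, and 47 in a fit to the arrays of this time alone. Replicate numbers tied the arrays of both treatments at 2 h and 4 h. With the number as a block at every time, 391 genes passed at 2 h (258 higher, 133 lower). At 24 h equal numbers were not tied (correlation -0.13), yet the same fit gave 2322 genes against 799 without the block. Crossed numbers at 24 h gave 2459. The larger count at 2 h can therefore not be assigned to the pairing.

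At 2 h, 19 of the 30 receptor targets rose, 0 fell and 11 did not pass (21 higher adjusted over the list alone, median 1.31, camera adjusted p = 3.7e-97). Of 24 cytokines and chemokines, 5 fell and 19 did not pass (7 lower adjusted over the list alone, median -0.23, adjusted p = 1.7e-09), with Ccl4 and Lif (-1.15) among them. Of 24 reactive astrocyte genes, 5 rose and 19 did not pass (6 and 1 lower adjusted over the list alone, median 0.01, adjusted p = 0.00092), Sphk1 (1.81) and Slc10a6 (at least 2.23-fold) included. In the astrocyte list Gjb6 alone of 24 was called (2 adjusted over the list alone, median 0.05, adjusted p = 6e-04). It was also the 1 gene of 21 called in the tight and gap junction list (1 adjusted over the list alone, median 0.06, adjusted p = 0.025). Growth factors had 0 of 28 called (5 lower adjusted over the list alone, median -0.02, adjusted p = 0.044), the largest being the neurotrophin Bdnf (-0.82, adjusted p = 0.057). For this list fry gave adjusted p = 0.054 and centring each array on its median 0.055.

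At 2 h, 3 further lists passed on 1 called gene each and lost the call with an estimated correlation. Interferon-stimulated genes had Irf1 lower (-0.90) of 22 (1 adjusted over the list alone, median -0.06, adjusted p = 0.049, adjusted p = 0.16 with an estimated correlation and 0.19 by fry). Glucose handling had Pdk4 higher of 21 (2 adjusted over the list alone, median 0.01, adjusted p = 0.038, adjusted p = 0.071 with an estimated correlation and 0.076 with the replicate block). Heat shock genes had Hspb1 higher of 9 (1 adjusted over the list alone, median 0.05, adjusted p = 0.038, and adjusted p = 0.058 with an estimated correlation). The call of Hspb1 (1.46) ended without any of 4 of the 6 arrays, down to 1.15 without vehicle replicate 3 (adjusted p = 0.19).

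At 4 h Gjb6, Lcn2 and Bcat1 led the rises. Gjb6 rose 31.7-fold (4.98, SE 0.16, adjusted p = 3.6e-17), Lcn2 26.9-fold (4.75, SE 0.26), Bcat1 26-fold (4.70, SE 0.23), Fam107a 25-fold (4.64, SE 0.25), Fkbp5 24.6-fold (4.62, SE 0.18) and Plin4 16.3-fold (4.03, SE 0.21), with 3 arrays per treatment. Glul rose 4.28-fold (2.10, SE 0.31). Wnt7a (-2.50, SE 0.30, adjusted p = 2.5e-06), Ch25h (-2.47), Phlda1 (-2.15) and Cxcl10 (-2.14) fell. Per1 (2.33), Tsc22d3 (2.69), Per2 (0.79), the folate enzyme Mthfd2 (1.35), Hspa1a (1.32), Hdc (2.00) and Ntf3 (0.89) rose, while Dbp (-1.14) and Bdnf (-0.97) fell. The test called 488 genes, 1334 with the replicate block (657 higher, 677 lower) and 915 with array weights (493 higher, 422 lower), and the share of rises was lower in both fits.

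Of the 30 receptor targets, 19 rose at 4 h, 0 fell and 11 did not pass (21 and 1 lower adjusted over the list alone, median 1.61, camera adjusted p = 6.3e-75). At 4 h, 3 of 24 astrocyte markers rose and 21 did not pass (4 and 1 lower adjusted over the list alone, median 0.18, adjusted p = 2.3e-05): Gjb6, Glul and the aldolase Aldoc (0.71). Of 24 reactive astrocyte genes, 6 rose, 1 fell and 17 did not pass (7 and 1 adjusted over the list alone, median -0.03, mean 0.47, camera direction up, adjusted p = 0.00043), with Sphk1 at 2.54 and Slc10a6 at least 4.89-fold higher. Interferon-stimulated genes had 0 of 22 called (5 lower adjusted over the list alone, median -0.35, or -0.21 on the log2 of the deposited values, adjusted p = 1.9e-06). Of 21 junction and transport genes, 2 rose and 19 did not pass (3 adjusted over the list alone, median 0.08, adjusted p = 0.0094). Besides Gjb6 this was Cldn10 (0.96), which lost its call whichever 4 h array was left out (0.92 to 1.03, adjusted p from 0.063 to 0.13). Of 24 cytokines and chemokines, 5 fell and 19 did not pass (8 lower adjusted over the list alone, median -0.20, adjusted p = 9.3e-07, and adjusted p = 0.09 with an estimated correlation). Fry alone called the glucose handling (adjusted p = 0.00062), fatty acid and heat shock lists (0.022 each) at 4 h.

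**Figure D3:**
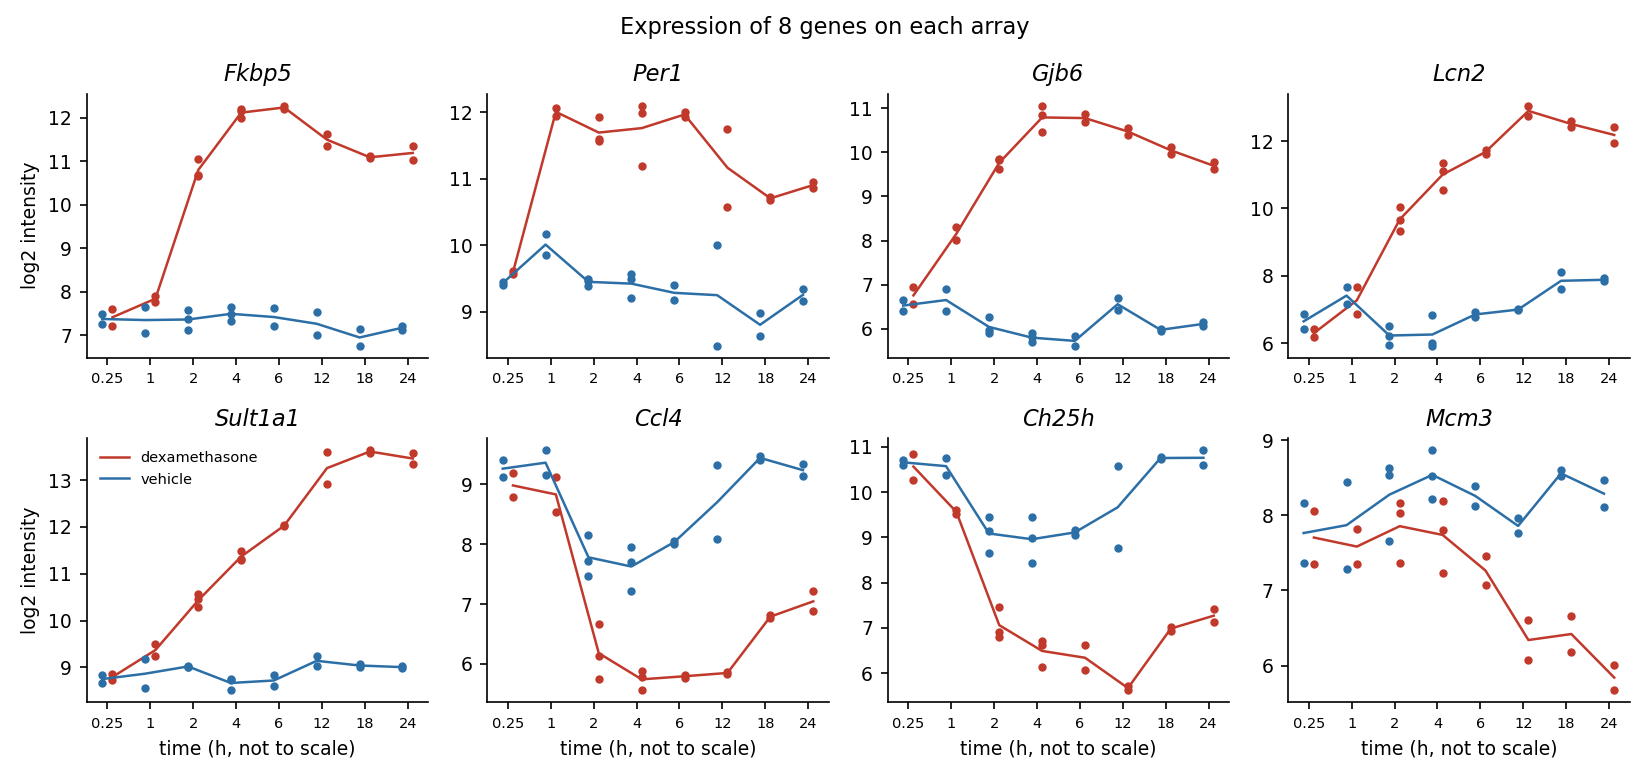
Log2 intensity of 8 genes on each array against hours of treatment, with dexamethasone and vehicle group means as lines and single arrays as points. Fkbp5 and Gjb6 had risen by 4.62 and 4.98 at 4 h, and Mcm3 had fallen by 2.45 at 24 h.

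After 6 h, Fam107a was 35.8-fold higher (5.16, SE 0.31, adjusted p = 1.8e-11), Gjb6 33-fold (5.04, SE 0.2), Lcn2 28.5-fold (4.83, SE 0.31) and Fkbp5 28.2-fold (4.82, SE 0.23), with 2 arrays per treatment. Ch25h (-2.77, SE 0.39, 6.8-fold), the osteoprotegerin gene Tnfrsf11b (-2.40, SE 0.23), Cxcl10 (-2.35) and Phlda1 (-2.24) fell. In the amino acid stress response the kinase-like gene Trib3 (-2.17, 4.51-fold) and the glutathione-degrading enzyme gene Chac1 (-1.82, 3.54-fold) fell. Per1 (2.68), Tsc22d3 (2.52), Pdk4 (3.47), Plin4 (4.17), Hdc (2.72), Cldn10 (1.61), Glul (2.45) and Cbs (1.71) rose, and Dbp fell (-1.12). The test called 429 genes, 206 and 203 without dexamethasone 6 h replicate 1 or 2 and 197 and 221 without vehicle replicate 1 or 2. Array weights gave 2305 (1079 higher, 1226 lower) and a fit to this time alone 2036 (1014 higher, 1022 lower), where rises were no longer in excess.

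At 6 h, 16 of the 30 receptor targets rose, 0 fell and 14 did not pass (19 and 1 lower adjusted over the list alone, median 1.47, camera adjusted p = 2.4e-63). Of 24 cytokines and chemokines, 6 fell and 18 did not pass (10 lower adjusted over the list alone, median -0.55, adjusted p = 1.3e-15), Ccl4 by at least 4.6-fold. Astrocyte markers had 4 of 24 higher and 20 not called (5 adjusted over the list alone, median 0.22, adjusted p = 2e-07). Of 24 reactive genes, 6 rose, 1 fell and 17 did not pass (7 and 2 adjusted over the list alone, median 0.02, adjusted p = 0.0068, 0.098 with the replicate block), Slc10a6 by at least 7.7-fold. Interferon-stimulated genes had 1 of 22 lower (3 adjusted over the list alone, median -0.33, adjusted p = 3e-04). Stress response genes had Trib3 and Chac1 lower of 20 (2 adjusted over the list alone, median -0.17, adjusted p = 0.0068).

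Cholesterol synthesis and uptake had 1 gene of 21 lower at 6 h, the squalene epoxidase Sqle (-0.73), which lost its call whichever 6 h array was left out (-0.61 to -0.85, adjusted p from 0.078 to 0.45). The list held 1 lower adjusted over the list alone (median -0.19, camera adjusted p = 0.005). Junction and transport genes had 3 of 21 higher (3 and 1 lower adjusted over the list alone, median -0.01, mean 0.35, camera direction up, adjusted p = 0.013, 0.064 with the replicate block). Immediate early genes had 1 of 19 lower (2 higher and 4 lower adjusted over the list alone, median -0.32, adjusted p = 0.011, and adjusted p = 0.39 with an estimated correlation). Fatty acid genes had Plin4 higher of 23 (2 adjusted over the list alone, median 0.17, adjusted p = 0.02). Glucose handling had 2 of 21 higher (2 and 1 lower adjusted over the list alone, median 0.07, adjusted p = 0.04). For both, adjusted p = 0.083 with an estimated correlation.

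At 12 h Lcn2 reached 60-fold (5.91, SE 0.31, adjusted p = 8.3e-13), and Cdc6, Mcm5 and Dbp fell beside Ccl4. Fam107a rose 27.8-fold (4.80, SE 0.31), Ipas at least 19.3-fold, Plin4 24.7-fold (4.62), Sult1a1 17.4-fold (4.12), Hspb1 11.9-fold (3.58) and Tsc22d3 10.4-fold (3.38), and Fkbp5 (4.23) and Per1 (1.91) rose as well, with 2 arrays per treatment. Ch25h was at least 14.2-fold lower, Ccl4 7.22-fold lower (-2.85), B3gat1, which makes a carbohydrate of cell adhesion, 6.15-fold lower (-2.62) and 4933407L21Rik 5.47-fold lower (-2.45). Dbp (-2.40), Nr1d2 (-2.09), Jun (-1.50), the replication licensing gene Cdc6 (-1.48), Mcm5 (-1.27) and Mcm2 (-1.24) fell. The ligand gene Gas6 (1.65), Igfbp3 (1.39), Ogn (1.22) and Ntf3 (1.06) rose, and the connexin 43 gene Gja1 fell (-0.79).

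Vehicle 12 h replicate 1 stood apart from vehicle 12 h replicate 2: 17 of 19 microglia markers were over 1 log2 unit higher in it (median 2.19), as were 9 of 14 oligodendrocyte markers (median 1.4) and 10 of 19 immediate early genes (median 1.05). Microglia genes lost their 12 h calls without it: Fcer1g went from -1.73 to -0.36, Lyz from -1.67 to -0.38, Aif1 from -1.56 to -0.46 and Cx3cr1 from -1.55 to -0.84, and the oligodendrocyte factor Sox10 from -2.36 to -0.52. Egr3 (-2.16 to -0.37), Egr1 (-1.57 to -0.12), Cxcl2 (-1.61 to -0.47) and Ccl3 (-1.54 to -0.47) did so too. The test called 1171 genes and 1113 without this array, 679 of them in both. It called 596 without dexamethasone 12 h replicate 2 (333 higher, 263 lower), 293 with array weights (169 higher, 124 lower) and 23 in a fit to the arrays of this time alone (23 higher, 0 lower). The excess of falls at 12 h did not hold in these 3 settings, but it did with the replicate block (1537 higher, 2298 lower).

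**Figure D4:**
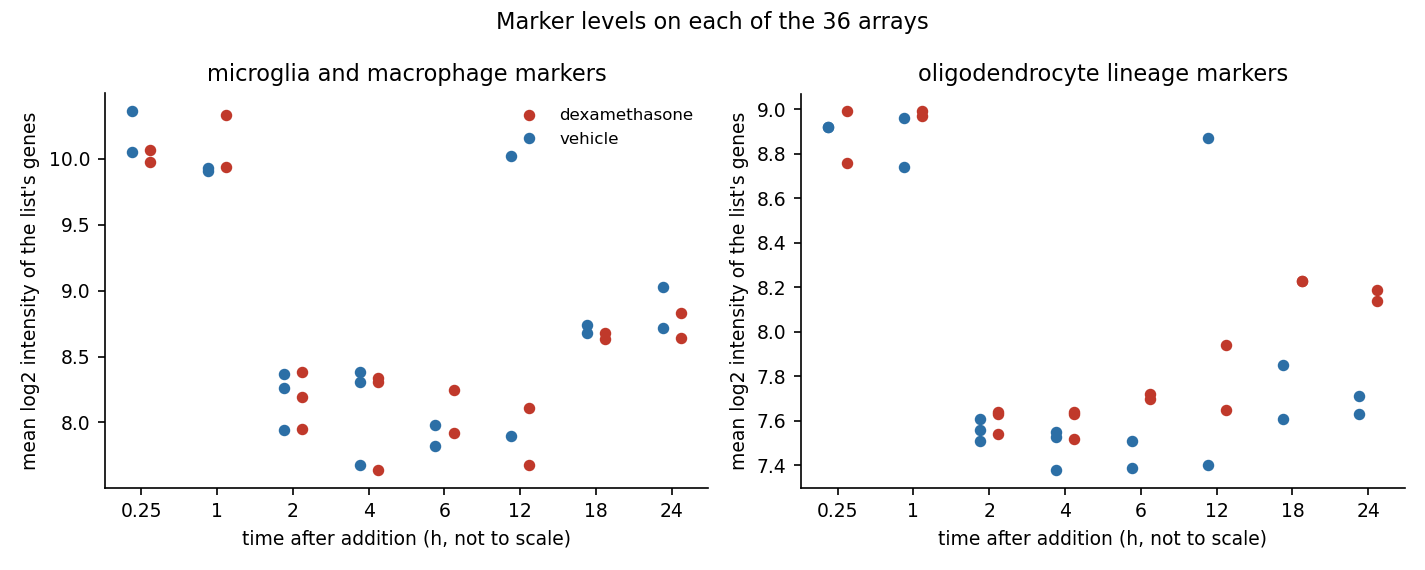
Mean log2 intensity of the microglia and the oligodendrocyte markers on each of the 36 arrays against hours of treatment, dexamethasone and vehicle in separate colours. Vehicle 12 h replicate 1 stands at 10.02 and 8.87, replicate 2 at 7.9 and 7.4.

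At 12 h, 21 of the 30 receptor targets rose, 0 fell and 9 did not pass (24 adjusted over the list alone, median 1.61, camera adjusted p = 1.7e-45). Of 24 reactive astrocyte genes, 6 rose and 18 did not pass (8 and 1 lower adjusted over the list alone, median 0.27, adjusted p = 9.4e-07, but 0.14 and adjusted p = 0.00013 without vehicle 12 h replicate 1), Amigo2 (1.41) among them. Of 28 growth factors and binding proteins, 4 rose and 24 did not pass (5 and 1 lower adjusted over the list alone, median 0.16, adjusted p = 0.0064, and 0.36 and adjusted p = 0.013 without that array). Heat shock genes had Hspb1 higher of 9 (3 adjusted over the list alone, median 0.20, adjusted p = 0.0088, and 0.11 and adjusted p = 0.047 without it). Extracellular matrix had 2 of 27 higher (2 adjusted over the list alone, median 0.17, adjusted p = 0.0064), but without vehicle 12 h replicate 1 the median was 0.14 and adjusted p = 0.24.

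At 12 h, 8 lists passed with the preset correlation and by fry (adjusted p up to 0.039) but not with an estimated correlation. Of 24 cytokines and chemokines, 7 fell and 17 did not pass (8 adjusted over the list alone, median -0.42, adjusted p = 1.2e-06, and adjusted p = 0.081 with an estimated correlation), with -0.26 and adjusted p = 0.022 without vehicle 12 h replicate 1. Of 30 cell division genes, 5 fell and 25 did not pass (5 adjusted over the list alone, median -0.21, adjusted p = 0.0088, and adjusted p = 0.12 with an estimated correlation). Of 24 astrocyte markers, 6 rose, 1 fell and 17 did not pass (6 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.0088, and adjusted p = 0.1 with an estimated correlation), with 0.23 and adjusted p = 0.0096 without that array. Fatty acid genes had 2 of 23 higher (3 adjusted over the list alone, median 0.21, adjusted p = 0.0064, and adjusted p = 0.053 with an estimated correlation). The stress response (0 of 20 called, 1 higher and 1 lower adjusted over the list alone, median 0.29, adjusted p = 0.019, and adjusted p = 0.054 with an estimated correlation) and the fibroblast list (Ogn of 11, 1 adjusted over the list alone, median 0.19, adjusted p = 0.035, and adjusted p = 0.19 with an estimated correlation) had adjusted p of 0.24 and 0.17 without vehicle 12 h replicate 1. Microglia markers fell in 6 of 19 (10 adjusted over the list alone, median -1.03, adjusted p = 6.1e-07, and adjusted p = 0.2 with an estimated correlation), with a median of -0.09 and adjusted p = 0.99 without that array. Ependymal markers had 6 of 8 lower and Hdc higher (7 and 1 adjusted over the list alone, median -0.90, adjusted p = 0.00055, and adjusted p = 0.19 with an estimated correlation), with -0.55 and adjusted p = 0.06 without it. Fry alone called the interferon (adjusted p = 0.0098) and junction lists (2e-04) at 12 h. Over all settings their medians ran from -0.21 to -0.05 and from -0.01 to 0.14.

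At 18 h, Folh1 and Sult1a1 stood among the largest rises, and Dbp, Nr1d2, Mcm3 and Cdc6 fell. Ipas was at least 26.4-fold higher, Fam107a 28.1-fold (4.81, SE 0.31), Lcn2 25.3-fold (4.66), Folh1 23.9-fold (4.58, SE 0.23) and Sult1a1 23.8-fold (4.57), while Fkbp5 (4.14), Tsc22d3 (2.61), Per1 (1.90) and Gjb6 (4.07) also rose, with 2 arrays per treatment. Ch25h fell 13.7-fold (-3.77, SE 0.39), Dbp 9.13-fold (-3.19, SE 0.17, adjusted p = 8.1e-13), Cxcl10 6.88-fold (-2.78) and Ccl4 6.29-fold (-2.65). Nr1d2 fell (-2.37) and the clock activator Npas2 rose (1.80). Mcm3 (-2.15), Cdc6 (-2.00), Tk1 (-1.99) and Mcm5 (-1.92) fell. Cldn11, a claudin of myelin sheaths, rose 10.2-fold (3.36, SE 0.48) and Enpp2 by 1.98. The test called 746 genes, 378 and 364 without dexamethasone replicate 1 or 2 and 367 and 383 without vehicle replicate 1 or 2, with 50% to 53.3% of them higher. Array weights gave 3841 and a fit to this time alone 3447.

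Of 30 cell division genes, 20 fell at 18 h, 0 rose and 10 did not pass (28 adjusted over the list alone, median -1.05, camera adjusted p = 2.2e-41). Of the 30 receptor targets, 17 rose and 13 did not pass (20 adjusted over the list alone, median 1.30, adjusted p = 2.4e-47). Of 24 astrocyte markers, 7 rose and 17 did not pass (8 and 1 lower adjusted over the list alone, median 0.46, adjusted p = 1.4e-09), Cbs (2.53) and Aldoc (1.55) among them. Of 24 reactive genes, 6 rose, 1 fell and 17 did not pass (8 and 1 adjusted over the list alone, median 0.17, adjusted p = 7.1e-07), with Hspb1 (3.06), Slc10a6 (at least 4.49-fold) and the serpin Serpina3n (1.86). Of 24 cytokines and chemokines, 5 fell and 19 did not pass (7 adjusted over the list alone, median -0.49, or -0.27 on the log2 of the deposited values, adjusted p = 1.1e-08). Junction and transport genes had 3 of 21 higher (4 adjusted over the list alone, median 0.25, adjusted p = 0.0013).

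Pdk4 (3.16) and Plin4 (3.58) rose at 18 h. Of 23 fatty acid genes, 4 rose, 1 fell and 18 did not pass (4 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.0013). Of 21 glucose handling genes, 3 rose and 18 did not pass (4 and 1 lower adjusted over the list alone, median 0.08, adjusted p = 0.0071). Interferon-stimulated genes had 1 of 22 lower (1 adjusted over the list alone, median -0.24, adjusted p = 0.035, and adjusted p = 0.12 with an estimated correlation). The oligodendrocyte list had Cldn11 and Enpp2 higher of 14 (3 adjusted over the list alone, median 0.15, or 0.09 on the log2 of the deposited values, adjusted p = 0.015, and adjusted p = 0.3 with an estimated correlation). The fibroblast list had Ogn (1.18) higher of 11 (1 adjusted over the list alone, median 0.25, adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation). The clock list (median -0.67, adjusted p = 0.0012 by fry), the heat shock list (0.0051) and the cholesterol list (0.022) passed by fry at 18 h, the cholesterol list with the replicate block as well (0.031).

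After 24 h, Ipas was at least 27.8-fold higher, Folh1 28.7-fold (4.84, SE 0.23), Fam107a 24.5-fold (4.62), Sult1a1 21.9-fold (4.45), Lcn2 19.8-fold (4.31) and Fkbp5 16.2-fold (4.01), with 2 arrays per treatment. Cldn11 was 14.9-fold higher (3.90, SE 0.48) and Enpp2 rose by 1.57. The glutamate transporter Slc1a2 (1.19), Serpina3n (2.16) and the fatty acid carrier Fabp5 (1.49) rose. Ch25h fell 11.2-fold (-3.49, SE 0.39), Mcm3 5.45-fold (-2.45, SE 0.39, adjusted p = 0.00014), Cxcl10 5.31-fold (-2.41), Tk1, the thymidine kinase of dividing cells, 4.83-fold (-2.27), Top2a by -2.13 and the adhesion gene Vcam1 by -1.13. Tsc22d3 rose (2.57), as did Per1 (1.65), whose call ended without vehicle replicate 1 (1.56, adjusted p = 0.056). Nr3c1 did not pass (-0.74, SE 0.41, adjusted p = 0.53). The test called 799 genes, 516 without dexamethasone 24 h replicate 1 (268 higher, 248 lower) and 466 and 446 without vehicle replicate 1 or 2.

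Of 30 cell division genes, 26 fell at 24 h, 0 rose and 4 did not pass (28 adjusted over the list alone, median -1.63, camera adjusted p = 2e-58). Of the 30 receptor targets, 16 rose and 14 did not pass (20 adjusted over the list alone, median 1.24, adjusted p = 7.7e-36). Of 24 reactive genes, 8 rose, 1 fell and 15 did not pass (9 and 2 adjusted over the list alone, median 0.19, adjusted p = 4e-06). Of 24 astrocyte markers, 6 rose, 1 fell and 17 did not pass (8 and 1 adjusted over the list alone, median 0.32, adjusted p = 4e-06), with Gjb6 (3.58), Cbs (2.22) and Glul (2.17). Junction and transport genes had 2 higher and 1 lower of 21 (5 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0062).

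Pdk4 (3.11) and Plin4 (3.29) stood high at 24 h in lists whose calls were lost with an estimated correlation. Of 24 cytokines and chemokines, 5 fell and 19 did not pass (5 adjusted over the list alone, median -0.27, adjusted p = 8.7e-05, and adjusted p = 0.15 with an estimated correlation). Fatty acid genes had 3 higher and 1 lower of 23 (4 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.011, and adjusted p = 0.07 with an estimated correlation). Glucose handling had 3 of 21 higher (4 and 1 lower adjusted over the list alone, median 0.13, adjusted p = 0.035, and adjusted p = 0.1 with an estimated correlation). Immediate early genes had 2 of 19 higher (2 adjusted over the list alone, median 0.38, adjusted p = 0.035, and adjusted p = 0.47 with an estimated correlation). The oligodendrocyte list had Cldn11 and Enpp2 of 14 (2 adjusted over the list alone, median 0.19, or 0.11 on the log2 of the deposited values, adjusted p = 0.035, and adjusted p = 0.41 with an estimated correlation). The fibroblast list had Ogn (1.09) of 11 (2 adjusted over the list alone, median 0.25, adjusted p = 0.0498, and adjusted p = 0.25 with an estimated correlation). Fry also called the corticosteroid receptor and heat shock lists at 24 h (adjusted p = 0.0058 and 0.00065), the former with the replicate block too (0.043).

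Responses of Gpx3, Sult1a1, Rab15 and other single genes at 12, 18 and 24 h differed from those at 1, 2 and 4 h. The secreted glutathione peroxidase Gpx3 had a response of 0.07 early and 3.87 late (difference 3.8, SE 0.39, adjusted p = 2.5e-07), Galnt15 (listed as Galntl2), a glycosyltransferase, 0.16 and 3.12 (2.96), and Sult1a1 1.54 and 4.38 (2.84). For Prodh the values were 1.47 and 4.10 (2.63). In the other direction, the vesicle gene Rab15 went from 0.20 to -2.07 (-2.27, SE 0.17, adjusted p = 1.7e-09), the clock repressor Ciart (listed as Gm129) from 1.07 to -1.19 (-2.26) and Fam216b (listed as AU021034) from 0.07 to -2.17 (-2.24). The cation channel Trpc7 went from -0.15 to -2.16 (-2.01), Ch25h from -1.84 to -3.75 (-1.91) and Ccno, a cyclin of ciliated cells, from -0.14 to -2.04 (-1.90). For Ipas the fitted difference (3.07) is no exact size, since 7 of its 12 group means lay under the background level, and raising those to that level gave 1.6 and 4.6 (3). Done likewise with 1 group each, the difference was -2.19 for Ciart, -1.92 for Trpc7 and -1.86 for Ch25h. Lcn2 (2.27), Fam107a (1.56), Fkbp5 (1.28) and Tsc22d3 (0.82) had larger late responses. With 2 and 4 h alone as early times Lcn2 kept its call (0.86, adjusted p = 0.047), and Fam107a (0.81, adjusted p = 0.098), Fkbp5 (0.10, adjusted p = 0.93) and Tsc22d3 (0.42, adjusted p = 0.2) lost theirs. For Per1 no difference was called (-0.37, adjusted p = 0.65). Dbp (-1.74), Nr1d2 (-1.51), Arntl (1.43) and Npas2 (0.95, or 0.49 with no background correction) differed among the clock genes, whose list did not pass (median -0.14, adjusted p = 0.47). The difference was called for 1009 genes (385 higher late, 624 lower late), and for 2807 with the replicate block (1129 higher, 1678 lower).

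Of 30 cell division genes, 23 had a lower late response, 0 a higher one and 7 were not called (28 lower adjusted over the list alone, median -0.90, camera adjusted p = 2.8e-36), with Cdc6 at -1.67 and Mcm2 at -1.51. Of 24 reactive astrocyte genes, 8 were higher late and 16 not called (8 adjusted over the list alone, median 0.27, adjusted p = 2.3e-06), Hspb1 (2.14) and Serpina3n (1.22, but 0.79 with 2 and 4 h alone as early times) among them. Fatty acid genes had 2 higher and 1 lower of 23 (4 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.0011, and 0.23 and adjusted p = 0.00072 without vehicle 12 h replicate 1). Cholesterol genes had 0 of 21 called (0 adjusted over the list alone, median 0.17, adjusted p = 0.01, and 0.26 and adjusted p = 0.0095 without the 12 h arrays). Of 28 growth factors, 4 were higher, 3 lower and 21 not called (9 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.0077). Leaving out the 12 h arrays gave 0.19 and adjusted p = 0.12, and the log2 of the deposited values a median of 0.11. Of 30 receptor targets, 8 were higher, 1 lower and 21 not called (12 and 1 adjusted over the list alone, median 0.16, adjusted p = 1.3e-07), but with 2 and 4 h alone as early times the median was -0.09 and adjusted p = 0.28. Of 24 astrocyte markers, 5 were higher, 1 lower and 18 not called (6 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.0011), with 0.19 and adjusted p = 0.071 for the same early times.

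Chemokine, microglia, fibroblast and ependymal lists lost their late-minus-early call with an estimated correlation. By fry the fibroblast and ependymal lists passed (adjusted p = 0.0048 and 0.012) and the chemokine and microglia lists did not (0.067 and 0.17). Cytokines and chemokines had 4 lower of 24, such as Ccl4 (-1.23) and Vcam1 (-0.94, 5 adjusted over the list alone, median -0.20, adjusted p = 0.01, and adjusted p = 0.34 with an estimated correlation), and without vehicle 12 h replicate 1 the median was -0.12 and adjusted p = 0.1 (-0.09 and 0.011 without the 12 h arrays). With 2 and 4 h alone as early times the list (-0.2, adjusted p = 0.093) and Ccl4 (-0.82, adjusted p = 0.089) lost their calls. Microglia markers had 1 lower of 19 (1 adjusted over the list alone, median -0.52, adjusted p = 0.0011, and adjusted p = 0.4 with an estimated correlation), with -0.15 and adjusted p = 0.25 without that array and -0.11 and 0.15 without the 12 h arrays. Fibroblast markers had 2 higher of 11, Ogn (0.95) among them (4 adjusted over the list alone, median 0.31, adjusted p = 0.0011, and adjusted p = 0.054 with an estimated correlation). Ependymal markers had 3 lower of 8, Tekt1 at -1.50 among them (7 and 1 higher adjusted over the list alone, median -0.54, adjusted p = 0.00023, and adjusted p = 0.17 with an estimated correlation), with -0.31 and adjusted p = 0.0092 without the 12 h arrays. Immediate early genes (median 0.18, adjusted p = 0.089) and oligodendrocyte markers (-0.04, adjusted p = 0.38) did not pass, but did without vehicle 12 h replicate 1 (0.35, adjusted p = 0.00027, and 0.01, adjusted p = 0.011) and without the 12 h arrays (0.41, adjusted p = 4e-04, and 0.1, adjusted p = 0.0067). By fry the heat shock list (median 0.12, adjusted p = 0.003) and the junction list (0.08, adjusted p = 0.018) passed, the former also with each array centred on its median (0.047) and the latter without the 12 h arrays (0.038).

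A test across all 8 times called 566 genes whose response was not the same at every time. Sult1a1 and Ipas had the smallest adjusted p (5.9e-12 each), followed by Gjb6 (1.7e-11), Fkbp5 (2.3e-11), Folh1 (4.4e-11) and Lcn2 (1.8e-10). At 0.25 h their responses ran from -0.35 for Lcn2 to 0.22 for Gjb6 and none was called; at 12 h all 6 were called higher, Lcn2 by 5.91 and Gjb6 by 3.91. The test does not say which times differ.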

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

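The tests on vehicle 12 h replicate 1, on the loss of microglia or oligodendrocyte lineage cells and on the 0.25 h and 1 h cultures, and the fits without the 12 h arrays or without the 0.25 h and 1 h arrays, were chosen after the results were seen; the other tests of this part were planned. What draws attention here is a response to dexamethasone that differed between times by a direct test.

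Gpx3, Galnt15 and Sult1a1 were among the genes that rose more at 12, 18 and 24 h than at 1, 2 and 4 h. Rab15 (0.20 early, -2.07 late) and Ccno (-0.14 early, -2.04 late) were among those with a negative difference, which fell late. The late-minus-early difference was 3.8 for Gpx3, 2.96 for Galnt15, 2.84 for Sult1a1 and 2.63 for Prodh. It was -2.27 for Rab15, -2.26 for Ciart, -2.24 for Fam216b, -2.01 for Trpc7, -1.91 for Ch25h and -1.90 for Ccno. The fitted difference of 3.07 for Ipas, a probe for Hif3a, is no exact size, since 7 of its 12 group means lay under the background level, nor are those for Ciart, Trpc7 and Ch25h, with 1 such group each. In all, 1009 genes differed late minus early, 926 without the 12 h arrays and 793 without the 0.25 h and 1 h arrays. Across all 8 times 566 genes differed, with the smallest adjusted p for Sult1a1 and Ipas (5.9e-12 each), Gjb6 (1.7e-11), Fkbp5 (2.3e-11), Folh1 (4.4e-11) and Lcn2 (1.8e-10). Across the remaining times, 589 genes differed without the 12 h arrays and 400 without the 0.25 h and 1 h arrays.

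Among the lists, the median late-minus-early difference was 0.16 for receptor targets, 0.24 for astrocyte markers, 0.27 for reactive astrocyte genes, 0.15 for fatty acid use, 0.17 for cholesterol synthesis, 0.17 for growth factors and 0.31 for fibroblast markers. It was -0.9 for cell division, -0.2 for cytokines and chemokines, -0.52 for microglia markers and -0.54 for ependymal markers. With an estimated correlation the calls of cytokines (adjusted p = 0.34), microglia (0.4), ependymal (0.17) and fibroblast markers (0.054) were lost, and by fry those of cytokines (0.067) and microglia markers (0.17). Without vehicle 12 h replicate 1 microglia markers (-0.15, adjusted p = 0.25) and cytokines (-0.12, adjusted p = 0.1) lost theirs. Receptor targets (-0.09, adjusted p = 0.28), cytokines (-0.2, adjusted p = 0.093) and astrocyte markers (0.19, adjusted p = 0.071) did so without the 0.25 h and 1 h arrays, and growth factors (0.19, adjusted p = 0.12) and microglia markers (-0.11, adjusted p = 0.15) without the 12 h arrays.

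Chance was tested by regrouping the samples. For late minus early and for the test across times, the replicate-number differences of dexamethasone and vehicle were dealt to the times anew. This is the fit with the replicate block, which called 2807 genes late minus early and 2098 across times. Of 100 splits, the real one included, only the real one gave as many (highest other 202 late minus early and 1110 across times). Chance can be excluded for the counts of that fit only. The 1009 and 566 genes of the main fit were not regrouped, and replicate numbers counted as paired only at 2 h and 4 h. For the average of the 8 times, of 100 splits only the real one gave 2439 genes or more. The highest other gave 1625. That split kept 18 of 36 arrays on their own side and parted 3 of 8 times by replicate number. Further splits gave 864, 711, 647 and 637, while the median of the other splits was 0. Chance can therefore be excluded for the size of the count of 2439 only, not for its single genes. At 2 h (real 146, highest other 3) and 4 h (real 488, highest other 0), 10 splits are too few for a share under 0.05.

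Cell division genes fell late under dexamethasone. The 12 h arrays did not make the difference, since without them its median was -1.32. A broad loss of microglia or oligodendrocyte lineage cells is argued against by their markers. At 18 h and 24 h the marker medians reached at most 0.068 of the cell division median on the falling side. Only 7 of 14 oligodendrocyte markers lay above background on all arrays. Both lists mark whole lineages, so they cannot tell whether only the dividing cells among them were lost. Low division in early vehicle cultures, which would leave nothing to fall, is argued against by a vehicle level of 1 to 4 h that lay 0.06 above that of 12 to 24 h, though 1 h alone (10.31) lay under 12 h (10.45), 18 h and 24 h; without the 0.25 h and 1 h arrays the median difference was -0.94. Slower division of the cultured astrocytes under prolonged dexamethasone is a biological hypothesis that no test here decides; levels under dexamethasone were 9.34 at 18 h and 9.06 at 24 h against 10.5 and 10.64 in vehicle.

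Microglia and oligodendrocyte markers stood high in vehicle 12 h replicate 1. Cells of other types in that culture stay open and untested, since the share of high markers only restates the pattern: 89.5% of the microglia markers lay over 1 log2 unit above replicate 2, abundant ones included (Lyz 14.71 against 12.13, Laptm5 13.08 against 10.99, Fcer1g 11.88 against 9.13), as did Pdgfra (11.2 against 7.99) but not Olig1 (14.94 against 15.02). A biological explanation, a fall of these markers under dexamethasone, could not part the vehicle arrays of 12 h from each other. Its test therefore does not bear on their difference. The median response of the microglia markers was -0.05 at 18 h and -0.09 at 12 h against vehicle replicate 2 alone. A wrong label cannot be told apart. Over 5 sex-linked genes the nearest 0.25 h or 1 h array, vehicle 0.25 h replicate 1, lay at a distance of 1.06. That was 1.44 times the largest distance within a pair of those times, but dexamethasone 12 h replicate 1 lay farther away (1.32). Over all genes the closest array was vehicle 0.25 h replicate 1 (r = 0.9875 across genes, 0.9641 with vehicle 12 h replicate 2). The vehicle 0.25 h arrays correlated with each other at 0.9753.

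Microglia markers in vehicle cultures of 0.25 h and 1 h lay 1.93 above those of 2 to 24 h. Oligodendrocyte markers lay 1.46, ependymal markers 0.6 and astrocyte markers 0.52 above. Vehicle 12 h replicate 1 was left out of these comparisons. The lowest early microglia level was 9.91 and the highest later one 9.03, in 4 against 13 vehicle arrays. The array left out stood above that lowest early level, so the separation holds only without it. For astrocyte markers the lowest early and highest later levels were 10.71 and 10.59, and ependymal markers overlapped (10.03 and 10.22). Neuron (-0.17), endothelial (0.05) and fibroblast markers (0.12) differed little, though only 2 of 10 endothelial markers lay above background on all arrays. Cultures of another cell mixture may have served for these times; time and culture cannot be told apart, since the labels name no culture batch. No biological explanation was tested.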

How the results depend on the processing

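Leaving out the 12 h arrays or the 0.25 h and 1 h arrays, the crossed block at 24 h and the list counts at 12 h and late minus early without vehicle 12 h replicate 1 were chosen after the results were seen. Signal over background, not depth, limits the dim genes; with 1 array left in a group, it is assumed to vary like the other groups. None of 416 called named results turned direction; 383 kept their call with array weights, all with the replicate block, 400 with no filter and 375 with the 1.5-fold minimum. The slide block and neqc were not run. Scalings moved the median of all genes by at most 0.053, and list medians by up to 0.22: cytokines at 18 h went from -0.49 to -0.27 on the log2 of the deposited values.

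The cause was not tested for any value that follows, apart from the 1.5-fold minimum, which only removes genes. Array weights gave 915 genes at 4 h, 2305 at 6 h, 293 at 12 h and 3841 at 18 h. These weights, lower for arrays of larger spread, were 0.38 to 0.439 at 12 h and 2.503 to 3.258 at 6 h and 18 h. The main fit shares the spread of a gene over all times, so its order of the times by count depends on that choice. The replicate block gave 4984 for the average, 43 at 1 h, 391 at 2 h, 1334 at 4 h, 1084 at 6 h, 3835 at 12 h, 1925 at 18 h, 2322 at 24 h, 2807 late minus early and 2098 across times; crossed numbers at 24 h gave 2459. The 1.5-fold minimum gave 454 for the average. Arrays of 1 time alone kept 190 of 267 named calls and gave 0 at 1 h, 47 at 2 h, 2036 at 6 h, 23 at 12 h and 3447 at 18 h. Other settings gave 1983 to 3262 genes for the average, 11 to 16 at 1 h, 138 to 178 at 2 h, 460 to 575 at 4 h, 366 to 498 at 6 h, 1043 to 1290 at 12 h, 693 to 846 at 18 h, 745 to 1105 at 24 h, 793 to 1183 late minus early and 400 to 704 across times.

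With single arrays left out the counts ran from 2085 to 2658 for the average, 0 to 0 at 0.25 h, 1 to 7 at 1 h, 106 to 138 at 2 h, 366 to 415 at 4 h, 197 to 221 at 6 h, 596 to 1409 at 12 h, 364 to 383 at 18 h, 446 to 606 at 24 h, 793 to 1282 late minus early and 444 to 798 across times. Lists past the threshold ran from 8 to 11 for the average . Late minus early only vehicle 12 h replicate 1 was left out for the lists, and 11 passed. An estimated correlation left 1 list at 1 h, 5 at 12 h, 5 at 24 h and 7 late minus early, and fry 1 at 1 h. Without vehicle 12 h replicate 1, 8 lists passed at 12 h, and the microglia list, whose median was then -0.09, turned its test direction (adjusted p = 0.99). Over lists and settings other than single arrays left out, 416 calls were kept, 73 lost and 24 gained.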

Other observations

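The division of the cell division list into S phase and mitosis genes and the look at vehicle levels were chosen after the values were seen.

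At 12 h some DNA replication genes were called lower and no mitosis gene was called. Of 13 S phase genes, among them Mcm3, Cdc6 and Tk1, 5 were lower at 12 h (median -0.62), 11 at 18 h (-1.49) and 11 at 24 h (-1.47). Of 13 mitosis genes, 0 were called at 12 h (median 0.15), 7 were lower at 18 h (-1.03) and 12 at 24 h (-1.64). Up to 6 h neither part had a called gene. The difference between the parts was not tested, so an order of the falls is not shown. The camera call of the whole list at 12 h was lost with an estimated correlation (adjusted p = 0.12).

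Clock genes moved in both directions. Arntl, which encodes the clock activator BMAL1, was 0.99 higher at 12 h and 1.65 at 18 h and not called at 24 h (0.53), while Nr1d2 was lower at 12 h (-2.09) and 18 h (-2.37) and at 0.03 at 24 h. Per2 rose at 4 h (0.79) and fell at 18 h (-0.80). Ciart (listed as Gm129) rose at 4 h (1.31) and fell at 12 h (-1.34) and 18 h (-1.95). Of the 14 clock genes, 3 were higher and 4 lower at 18 h (4 and 7 adjusted over the list alone, median -0.67), with adjusted p = 0.1 by camera and 0.0012 by fry.

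In vehicle cultures, immediate early genes had a mean log2 level of 10.38 (SD 0.15, 2 arrays) at 1 h against 9.22 at 0.25 h, 9.57 at 2 h and 9.05 at 18 h. The 12 h level was 9.64 (SD 0.89), with replicate 1 above replicate 2 by a median of 1.05. Handling of the cultures is not described by time, and the difference was not tested. Across genes, which are not independent replicates, arrays of 1 group correlated at 0.9962 and 0.9959 at 6 h and 0.9966 and 0.9958 at 18 h, and the lowest correlation between any pair of arrays was 0.934.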
